A study of Mus musculus with 6 samples.

How the data were processed

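RNA-seq libraries of primary mouse microglia, the resident macrophages of the brain, were analysed from 6 RNA samples. Per the labels' protocols, brains of 3-day-old ICR mice were pooled (12 animals), mixed glia were grown in flasks, and microglia were shaken off and replated, with more than 92% of cells positive for CD11b by flow cytometry. The cells received FTY720 (fingolimod, a sphingosine analogue that acts on sphingosine-1-phosphate receptors once phosphorylated) at 1 µM for 4 h, alone in 3 libraries and together with lipopolysaccharide (LPS, a bacterial cell wall component sensed through Toll-like receptor 4) at 10 ng/ml in 3 libraries. Per the labels' protocols the replicates were independent RNA samples. Whether they came from separate pools of animals or from separate cultures is not given in the sources used here. The p-values therefore measure the spread between these RNA samples. Per the labels' protocols, ribosomal RNA was depleted from total RNA, strand-specific libraries were made with random primers, and they were sequenced on an Illumina HiSeq2000.

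The authors deposited 1 table of raw read counts per library, with gene symbols and 3 count columns (both strands together, and each strand), in the layout of the STAR aligner's gene counts. The submitters' processing notes name CASAVA 1.8.2, Trimmomatic 0.33, STAR 2.5.1, DESeq2 and the mouse genome build mm10; the gene annotation and the settings of each step are not given in the sources used here. Such counts hold uniquely mapped reads only, so reads shared between near-identical copies such as pseudogenes and paralogs were not counted. The deposited counts of the strand that carried 98.4% to 98.9% of the gene reads in every library were used as sense counts, and the other strand was examined separately. Rows that name no gene were left out of library sizes and tests. These rows held, as shares of all reads listed, 24.4% to 27.0% unmapped, 7.69% to 8.15% multimapping, 42.2% to 44.5% outside annotated exons on the sense strand and 0.075% to 0.114% ambiguous reads.

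Gene reads numbered 2431775 to 3454647 per library. Rn45s, the ribosomal RNA precursor, took 20.5% to 48.8% of them, and with Lars2 and Mir6236, which collect rRNA-like reads, 28.8% to 59.0%; 1340915 to 2116218 reads per library remained for other genes. A count of 0 allows up to 3 reads, which is 0.868 to 1.23 CPM of a library's gene reads. Intervals and floors cover counting error only, since the reads carry no molecular identifiers.

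Counts were tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood test, with TMM factors and filterByExpr at its defaults (minimum count 10), which kept 10124 of 24411 genes. Adjusted p-values are Benjamini-Hochberg values over the genes tested, with a threshold of 0.05. A standard error (SE) is the absolute log2 fold change divided by the square root of the F statistic. CPM values were scaled with the TMM factors, and log2 CPM used a prior count of 2. Fold changes of genes with no reads in a group are lower bounds against a floor of 3 reads summed over the group; with 1 to 3 reads, the ratio of summed reads is given with its exact 95% counting interval. A set of 24 gene lists was tested with camera (limma 3.58.1, preset correlation 0.01), again with an estimated correlation, and with fry. Before the data were examined, the lists, the main design, a first set of alternatives and the rule for naming genes were fixed. The rule took the 8 highest and 8 lowest fold changes among called genes with mean log2 CPM of at least 3, non-overlapping groups and a symbol that is not a predicted, clone, mitochondrial or ribosomal RNA name. It further took up to 2 called members of each list with the largest change and mean log2 CPM of at least 1 (or, with none called, the 2 most abundant), and 14 genes named in advance. Genes named outside that rule are said to be so. Positions, transcript lengths and GC content came from GENCODE M21 on GRCm38, the assembly also called mm10, which held 99.5% of the tested genes.

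On simulated counts drawn from the real means and library sizes, 34.4% of genes changed 1.5-fold, 79.5% changed 2-fold, 99.6% changed 4-fold and 100% changed 8-fold were called, as were 0.0761% of unchanged genes. Of 200 random lists of 20 genes, 0 reached a camera p under 0.05 there. The simulated genes varied independently of each other, so this does not show how often camera errs on lists of correlated genes. Over the 5 runs 48653 genes were unchanged, against 242 to 244 of each changed size. Trends of single libraries on length or GC content were not simulated. Far more genes were called in the real libraries, where the Benjamini-Hochberg threshold is therefore less strict. The simulated percentages do not give the sensitivity there. Replicates were compared by a chi-square test over genes, and every pair within a group differed by more than sampling noise. Replicates 1 and 2 lay closest (chi-square per degree of freedom 1.34 with FTY720 and 1.30 with LPS), against 1.70 to 4.92 for pairs with replicate 3. Such differences may also arise in library preparation, so the test cannot show that the RNA samples were independent. All 6 libraries were counted separately, as the labels' protocols call the replicates independent RNA samples. Replicate numbers were not treated as pairs.

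That first set held DESeq2 1.42.0, other scaling factors, other filters, unstranded counts, a replicate block, leaving out each library, an estimated inter-gene correlation and fry. After the data were seen, further alternatives were added: leaving out the rRNA-like genes, summing replicates 1 and 2, removing trends on transcript length and GC content, and removing each library's trend on mean expression. Also added then was a comparison of each list's median with 10000 lists of genes matched on transcript length and mean expression. Untreated cells and cells given LPS without FTY720 were not analysed here, so the effect of FTY720 itself cannot be estimated from these libraries.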

Results

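Gene expression was measured in 6 strand-specific RNA-seq libraries of primary mouse microglia, 3 treated with FTY720 at 1 µM for 4 h and 3 treated with FTY720 and LPS at 10 ng/ml for 4 h. Gene reads averaged 3051830 ± 369203 (SD, n = 3) with FTY720 and 2587180 ± 191232 (SD, n = 3) with LPS added (exact two-sided permutation p = 0.2, where 0.1 is the smallest p that 3 against 3 libraries allow). Of 16 library measures, 3 separated the groups (exact permutation p = 0.1 each, 0.53 adjusted): unmapped reads (24.8% with FTY720, 26.8% with LPS added), gene reads as a share of all reads (23.8% and 21.2%) and genes with at least 10 reads (10444 and 9326). The design asks how LPS changes the transcriptome of microglia that are exposed to FTY720. The first principal component carried 85.7% of the variance and separated the groups. Within groups the libraries correlated at 0.949 to 0.985 across genes, and between groups at 0.781 to 0.796. Along the second component (6.53%), FTY720 replicate 3 stood at -17.5, apart from the other libraries.

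Adding LPS to FTY720 raised the transcripts of inflammatory cytokines, chemokines and interferon-stimulated genes, and lowered those of S1pr1, S1pr2 and Tlr4. Tnf and Il1b, cytokines that drive acute inflammation, rose 86.4-fold (log2 fold change 6.43 ± 0.17, SE, n = 3 per group) and 123.5-fold (6.95 ± 0.15). All 12 tested chemokines and all 34 tested interferon-stimulated genes were higher. S1pr1, a receptor for sphingosine-1-phosphate and a target of phosphorylated FTY720, was 7.51-fold lower (-2.91 ± 0.17). Smaller changes followed mean expression, with a positive median log2 fold change in abundant genes and a negative one in scarce genes.

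Of 10124 genes tested with edgeR's quasi-likelihood test, 2362 were higher and 2297 lower with LPS at adjusted p under 0.05, and 860 were at least 2-fold higher and 971 at least 2-fold lower. Of the called genes, 235 overlapped between the groups. Over all 10124 tested genes the groups did not overlap for 5469, where chance gives 10%. The split of calls, 50.7% higher with TMM factors, depended on scaling: it was 38.8% with upper-quartile factors (1885 higher, 2969 lower) and 22.1% with total library size alone (761 higher, 2684 lower). Total library size includes the rRNA-like reads, which took 45.2% ± 15.3% of gene reads with FTY720 and 40.5% ± 3.74% with LPS (SD, n = 3). In that setting their uneven share adds spread between libraries to the values of all other genes. How many calls this changed was not tested. DESeq2 called 2041 genes higher and 1274 lower, 61.6% higher.

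The 8 highest named genes had few reads with FTY720 alone. Heatr9, a HEAT repeat gene, had 0 reads in the 3 FTY720 libraries and 665 with LPS, at least 322-fold higher; it lies on chromosome 11 (83511736 to 83522175, minus strand, GRCm38), 3602 bp downstream of Ccl5 (83525778 to 83530518, same strand). Cxcl10, an interferon-induced chemokine, had 1 read against 1093, a ratio of 1589 (95% counting interval 285 to 62830). Il12b, the p40 subunit of interleukin-12, had 1 against 764 (ratio 1111, 199 to 43930). Sele, the adhesion molecule E-selectin, had 1 against 478 (695, 124 to 27510), and Csf2, which encodes GM-CSF, had 1 against 388 (564, 101 to 22340). Cxcl1, a neutrophil-attracting chemokine, rose by a log2 fold change of 9.19 ± 0.20, from 2.03 ± 1.14 to 1122 ± 34.1 CPM (SD, n = 3). Rsad2, which encodes the antiviral enzyme viperin, rose by 8.54 ± 0.19 and the chemokine Ccl5 by 8.33 ± 0.18. For these genes the adjusted p lay between 1.16e-20 and 1.37e-14.

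The 8 lowest named genes fell by 8.64-fold to 21.5-fold. Lyl1, a haematopoietic transcription factor, was 21.5-fold lower (-4.43 ± 0.42), and Cxcr4, the receptor for the chemokine Cxcl12, was 16.3-fold lower (-4.02 ± 0.13; 577 ± 59.5 against 35.5 ± 3.56 CPM, SD, n = 3). Fbxo32, a ubiquitin ligase subunit, was 11.9-fold lower (-3.57 ± 0.21), Tifab was 10.6-fold lower (-3.40 ± 0.28) and the receptor gene Cd300lb was 10.4-fold lower (-3.38 ± 0.26). The cytokine Osm was 9.77-fold lower (-3.29 ± 0.19), Zfp36l2, an mRNA-destabilising RNA-binding protein, 9.03-fold lower (-3.18 ± 0.28) and the orphan receptor Mrgpre 8.64-fold lower (-3.11 ± 0.35). Adjusted p for these 8 genes lay between 3.07e-17 and 1.86e-07.

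**Figure D1:**
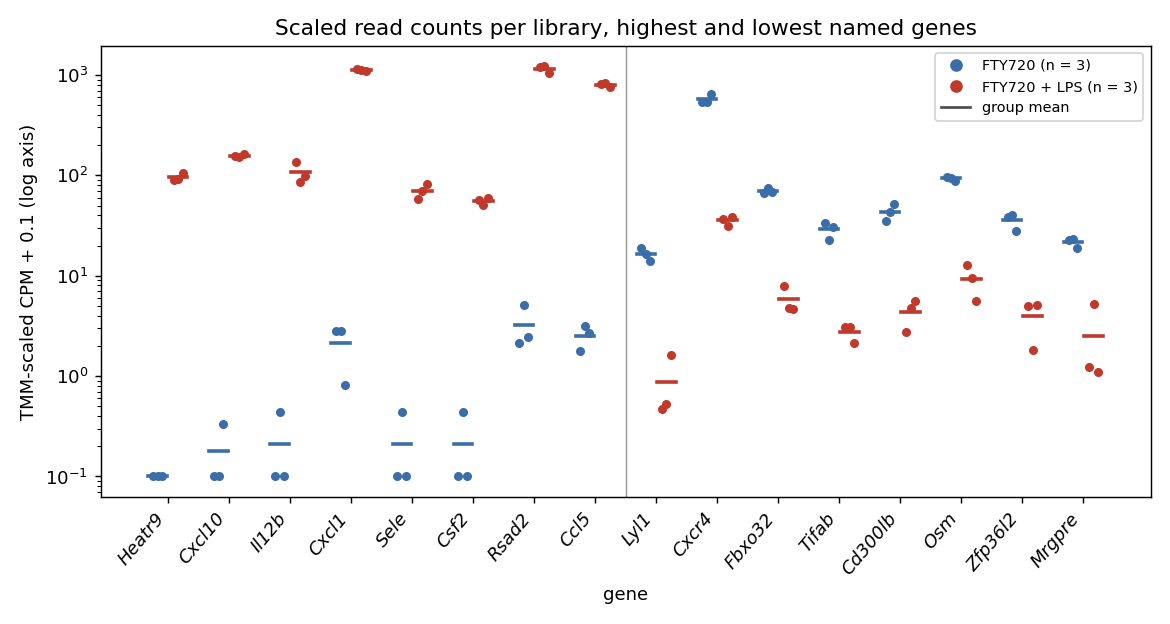
TMM-scaled CPM plus 0.1, on a log axis, for the 8 highest and 8 lowest genes of the naming rule. Points are libraries, lines group means (n = 3 per group); the 3 FTY720 libraries and the 3 libraries with LPS do not overlap for any of the 16 genes, and Heatr9 had 0 reads in the 3 FTY720 libraries.

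Log2 fold changes rose with mean expression across genes. The median was -0.33 in 1729 genes between 2 and 3 log2 CPM, -0.10 in 2326 genes between 4 and 5, 0.25 in 1049 genes between 6 and 7, and 0.73 in 270 genes above 8. Of those 270 abundant genes, 231 were higher and 8 lower. The control genes lay on the same side: Gapdh was 2.16-fold higher (1.11 ± 0.11), and Actb 1.44-fold higher (0.53 ± 0.11), although with the expression trend removed Actb was lower (-0.47, adjusted p = 0.00106), and with total library size alone it did not pass the test (0.21). Each list with 2 or more tested genes is therefore set beside the median of lists matched on transcript length and mean expression.

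**Figure D2:**
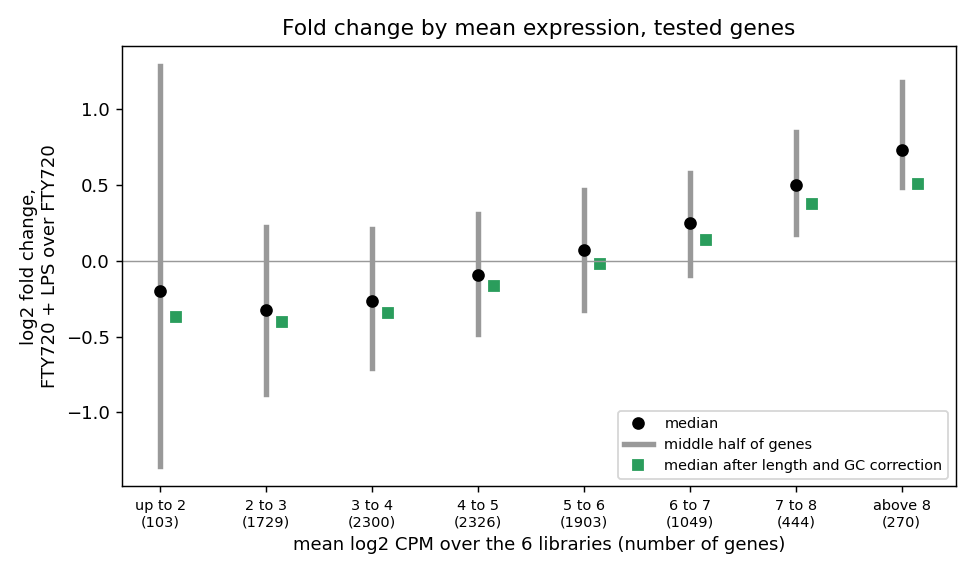
Log2 fold change of FTY720 + LPS over FTY720 for the 10124 tested genes by mean log2 CPM over the 6 libraries; dots are medians, grey bars the middle part from the lower to the upper quartile, and squares medians after length and GC correction. Medians rise from -0.33 between 2 and 3 log2 CPM to 0.73 above 8.

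Cytokine genes rose as a group. Of 16 tested, 13 were higher and 1, Osm, lower, with a median log2 fold change of 2.34 against 0.19 in matched lists (camera adjusted p = 6.69e-24, and 0.0298 with an estimated correlation). Il6 rose from 5 reads to 279 (6.24 ± 0.36). All 12 tested chemokines rose (median 4.77, matched 0.61, adjusted p = 2.41e-71, and 0.00516 with an estimated correlation), led by Cxcl10 and Cxcl1. All 34 tested interferon-stimulated genes rose (3.47, matched 0.08, adjusted p = 2.75e-75, and 0.0175 with an estimated correlation), among them Isg15, a ubiquitin-like antiviral modifier (8.17 ± 0.18), and Rsad2. Transcripts of Ifnb1, which encodes interferon beta, were too few to test, with 0 reads against 19 (at least 9.21-fold), as were those of the chemokine Cxcl9, with 0 against 40 (at least 19.4-fold); both were named after their counts were seen.

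NF-κB subunits and feedback inhibitors were higher in 19 of 21 tested members and lower in 2 (median 2.70, matched 0.18, camera adjusted p = 3.49e-29, and adjusted p = 0.0506 with an estimated correlation). Socs3, an inhibitor of cytokine receptor signalling, rose by 5.23 ± 0.19, and Tnip3, an NF-κB inhibitor, had 2 reads against 62 (ratio 45.1, 95% counting interval 12.0 to 380). Among 21 immediate-early genes 14 were higher and 5 lower (0.92, matched 0.23, adjusted p = 1.4e-06, and adjusted p = 0.226 with an estimated correlation), and with total library size alone 9 were higher and 5 lower. Dusp2, a MAP kinase phosphatase, stood at 4.90 ± 0.26 and the transcription factor Maff at 4.08 ± 0.21. The medians of the cytokine, chemokine, interferon and NF-κB lists do not move when members with at most 3 FTY720 reads are set to the lower end of their intervals. These members number 2, 1, 1 and 1 and all lie above their list's median, so little movement was possible.

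The LPS receptor complex split. Tlr4, the signalling receptor for LPS, fell 4.60-fold (-2.20 ± 0.19), whereas its co-receptor Cd14 rose 4.36-fold (2.12 ± 0.11). Of 18 Toll-like receptors and adaptors, 5 were higher and 5 lower (median -0.13, matched 0.14, mean -0.03, while camera pointed upward at adjusted p = 0.747), and with total library size alone 3 were higher and 6 lower. Among 9 inflammasome genes 4 were higher and 2 lower (median 0.31, matched -0.00, camera adjusted p = 0.0948, and 0.0325 with unstranded counts), and with total library size alone 2 were higher and 2 lower; Nlrp3, a sensor, rose by 2.93 ± 0.17 and Casp4, the mouse caspase-11 gene, by 2.59 ± 0.16.

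Sphingosine-1-phosphate genes moved in both directions. The median of the list lay just above its matched range (-0.31 to 0.31). The receptors S1pr1 and S1pr2 were 7.51-fold and 6.41-fold lower (S1pr2 -2.68 ± 0.27). The kinases that make sphingosine-1-phosphate diverged: Sphk1 rose by 2.67 ± 0.32 and Sphk2, which also phosphorylates FTY720, fell by 1.22 ± 0.22. Acer2, a ceramidase that releases sphingosine, rose by 3.54 ± 0.32. Over the 22 tested members 10 were higher and 4 lower, and camera did not call the list (median 0.32, matched -0.01, adjusted p = 0.367); with total library size alone 4 were higher and 4 lower.

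Enzymes that make nitric oxide, prostaglandins and itaconate were higher in 8 of 10 tested members and lower in none (0), with a median of 1.34 (matched 0.27, camera adjusted p = 4.4e-13, and 0.0175 with an estimated correlation). With total library size alone 5 were higher. Ptgs2, cyclooxygenase-2, rose by 5.34 ± 0.13 and Nos2, inducible nitric oxide synthase, by 4.55 ± 0.49 from 5 reads to 88. Of 14 antigen presentation and co-stimulation genes 9 were higher (1.05, matched 0.24, adjusted p = 7.3e-07, and 0.0321 with an estimated correlation). The co-stimulatory receptor Cd40 rose by 7.65 ± 0.25, and Cd74, the class II invariant chain, 5.64-fold from 27 reads to 106, whereas the class II genes H2-Aa, H2-Ab1 and H2-Eb1, named after their counts were seen, had at most 4 reads per group and were not tested. Of 8 alternative activation genes 5 were higher, and 3 with total library size alone (0.86, matched 0.14, adjusted p = 0.00202, and adjusted p = 0.0757 with an estimated correlation); Socs1, a feedback inhibitor of cytokine signalling, led with 4.11 ± 0.27, followed by the transcription factor Klf4 (1.54 ± 0.21).

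Metabolic and lysosomal lists changed by less. Although camera called them, their medians lay inside the matched ranges (glycolysis -0.02 to 0.65, NRF2 0.06 to 0.93, lysosome 0.48 to 0.84). Glycolysis genes were higher in 13 of 17 and lower in 2 (camera adjusted p = 0.00206, and adjusted p = 0.0757 with an estimated correlation), with the glucose transporter Slc2a1 at 2.13 ± 0.15 and hexokinase Hk2 at 1.30 ± 0.20; the 16 members with a known length had a median of 0.62 against 0.31 in matched lists. NRF2 antioxidant genes were higher in 6 of 9 and lower in 2 (0.62, matched 0.48, adjusted p = 0.00303, and adjusted p = 0.0781 with an estimated correlation), with thioredoxin reductase Txnrd1 at 2.14 ± 0.10 and the cystine transporter Slc7a11 at 1.30 ± 0.11. Lysosome and phagocytosis genes were higher in 20 of 26 and lower in 1 (0.56, matched 0.65, adjusted p = 9.88e-05, and adjusted p = 0.202 with an estimated correlation), including the protease Ctsl (1.17 ± 0.10) and the scavenger receptor Cd36 (1.02 ± 0.14). These 3 camera calls ended when the expression trend was removed (adjusted p = 0.351, 0.437 and 0.386, the last with the direction turned), where 7 glycolysis, 3 NRF2 and 7 lysosome genes were higher and 4, 3 and 8 lower. With total library size alone 6 glycolysis, 2 NRF2 and 2 lysosome genes were higher, the NRF2 list was not called (adjusted p = 0.0627) and Cd36 lost its call (0.64, adjusted p = 0.0775).

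Neither cholesterol list was called by camera in the main analysis. The synthesis and uptake median lay below its matched range (-0.11 to 0.50), at unadjusted percentile 1.31, while the efflux median lay inside its own (-0.12 to 0.81). Of 18 synthesis and uptake genes 4 were higher and 4 lower (median -0.15, matched 0.20, camera adjusted p = 0.747, downward, where fry pointed upward at adjusted p = 0.935); Insig1, which retains the sterol sensor in the endoplasmic reticulum, rose by 1.43 ± 0.11 and Fdft1, squalene synthase, fell by 0.81 ± 0.14. With total library size alone 1 of the 18 was higher and 4 lower, and with the expression trend removed 1 and 6. Among 8 liver X receptor and efflux genes 4 were higher and 3 lower (median 0.16, matched 0.34, but mean -0.17, with camera downward at adjusted p = 0.587); with total library size alone 0 were higher and 3 lower, and with the expression trend removed 1 and 3. The cholesterol exporters Abcg1 and Abca1 were 3.75-fold (-1.91 ± 0.18) and 2.82-fold lower, and this list was called downward once the expression trend was removed (adjusted p = 0.0228). Of 17 cell cycle genes 2 were higher and 2 lower (0.07, matched -0.31, adjusted p = 0.747), and with the expression trend removed 5 and 1; Pcna, the replication clamp, rose by 1.84 ± 0.12 and the mitotic kinase Aurka by 1.31 ± 0.32.

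Homeostatic microglia markers were mixed, with 8 of 19 higher and 1 lower (median 0.30, matched 0.28, camera adjusted p = 0.176); with total library size alone 2 were higher, and with the expression trend removed 5 were higher and 3 lower. Mertk, a receptor for engulfing dying cells, fell 3.55-fold (-1.83 ± 0.17), while the fractalkine receptor Cx3cr1 rose 2.15-fold (1.10 ± 0.18). P2ry12, an ADP receptor, was higher by 0.74 ± 0.29 (adjusted p = 0.0412), a call that ended in 10 alternatives (adjusted p 0.0546 to 0.412), among them DESeq2 (0.78, adjusted p = 0.157), total library size alone (0.41, 0.412), length and GC correction (0.44, 0.19), and the fits without FTY720 replicate 1 (0.75, 0.0786), FTY720 replicate 2 (0.62, 0.117) or FTY720_LPS replicate 2 (0.52, 0.235). Aif1, which encodes the microglial marker Iba1, rose 2.30-fold from 28 reads to 45 (adjusted p = 0.0521 without FTY720_LPS replicate 1, 0.0786 with DESeq2 and 0.0912 with total library size alone), and Itgam, which encodes CD11b, rose by 0.81 ± 0.13 (with total library size alone 0.49, adjusted p = 0.176).

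Markers of other brain cells moved apart. The oligodendrocyte-lineage and neuron medians lay below their matched ranges (-0.80 to 0.42 and -0.60 to 0.52), at unadjusted percentiles 1.44 and 2.05. Camera did not call the neuron list. The monocyte and border macrophage median, which camera called, lay inside its matched range (-0.22 to 1.18), as did the uncalled astrocyte and fibroblast medians. Oligodendrocyte-lineage markers were lower in 6 of 7 and higher in 0 (-0.92, matched -0.14, camera adjusted p = 0.00657, and adjusted p = 0.125 with an estimated correlation), including the transcription factors Olig2 (-2.47 ± 0.31) and Sox10 (-2.24 ± 0.51). Of 6 neuron markers 4 were lower (-0.62, matched -0.09, adjusted p = 0.0561, a list called under 6 camera alternatives at 0.0214 to 0.0498, among them without FTY720 replicate 1 at 0.0265; adjusted p = 0.296 with an estimated correlation), including Dcx (-1.16 ± 0.16) and Map2 (-0.93 ± 0.17). Astrocyte markers split, with 2 of 8 higher and 1 lower, or 1 and 2 with total library size alone (0.05, matched -0.30, adjusted p = 0.996): the gap junction gene Gja1 rose by 1.22 ± 0.23 and the glutamate transporter Slc1a2 fell by 1.30 ± 0.24. None (0) of 6 fibroblast and mural markers passed the edgeR test (0.33, matched -0.23, adjusted p = 0.747). Fn1 stood at 0.47 ± 0.22 (adjusted p = 0.0851). It was called without FTY720 replicate 2 (0.84, adjusted p = 0.000272) and after length and GC correction (0.80, adjusted p = 8.61e-05). Summing replicates 1 and 2 (adjusted p = 0.0101) or dropping the low-count filter (adjusted p = 0.00828) also gave a call for Fn1. Acta2 stood at 0.38 ± 0.17 (adjusted p = 0.0807) and was called without FTY720 replicate 2 (0.0119) or FTY720_LPS replicate 2 (0.0272). The 1 tested endothelial marker, Cdh5, rose by 1.62 ± 0.36 (camera adjusted p = 0.496), and 4 of 4 monocyte and border macrophage markers rose (0.92, matched 0.37, adjusted p = 0.0301, and adjusted p = 0.284 with an estimated correlation), among them Pf4 (1.13 ± 0.32) and Ms4a7 (1.00 ± 0.12); with total library size alone 0 of these 4 did, at 0.83 for Pf4 (adjusted p = 0.0993) and 0.65 for Ms4a7 (0.0649), and the list was not called (0.0624).

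**Figure D3:**
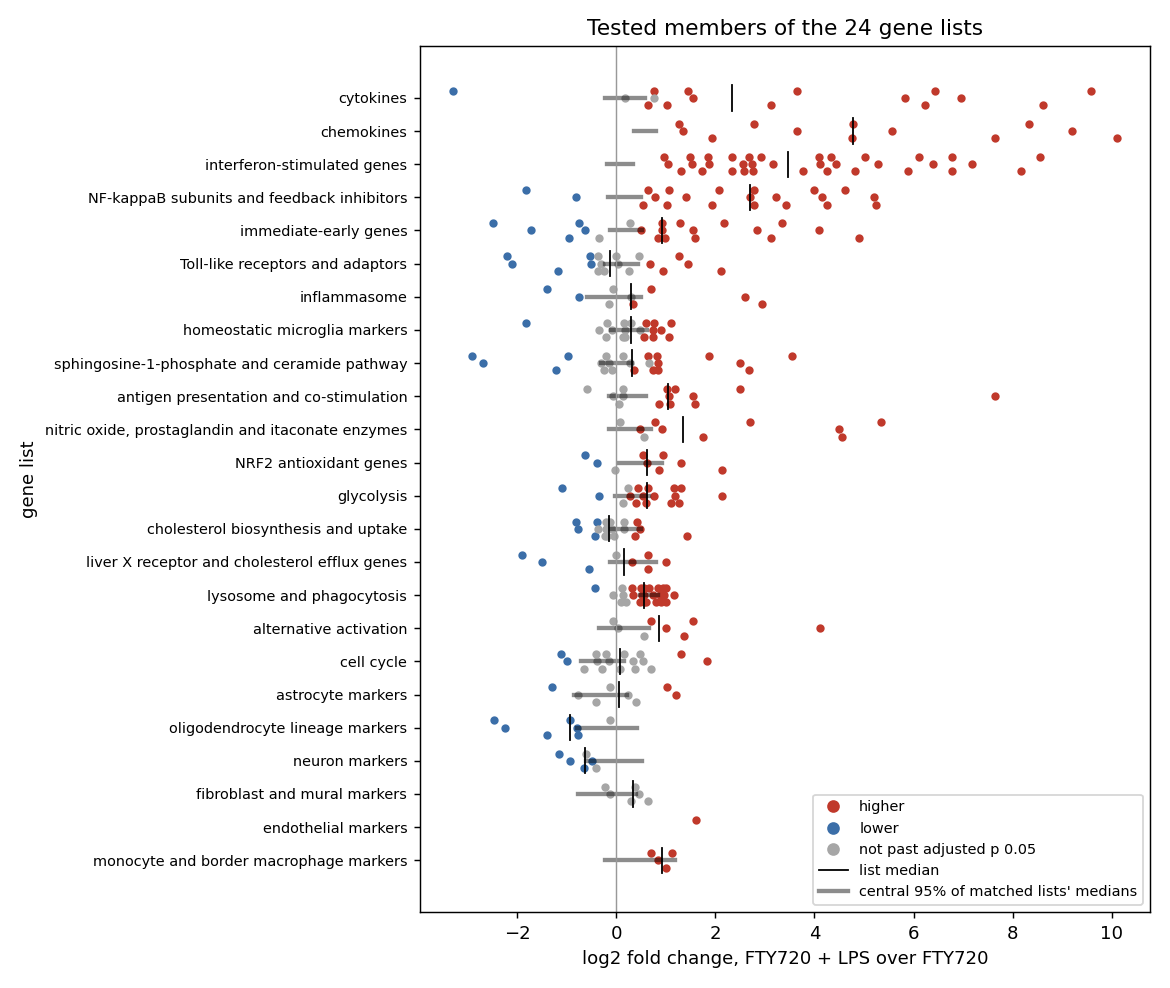
Log2 fold changes of FTY720 + LPS over FTY720 for the tested members of the 24 gene lists, coloured by the edgeR call; upright ticks are list medians and thick bars the central 95% of the medians of 10000 lists matched on length and mean expression (none for the endothelial list, with 1 gene). Chemokines (12 of 12) and interferon-stimulated genes (34 of 34) lie to the right of 0, and 6 of 7 oligodendrocyte-lineage markers are called to the left.

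Adjusted over the list alone, the counts equal those over all genes except for cytokines (14 higher), Toll-like receptors and adaptors (6 lower) and the cell cycle (1 lower). Camera called 13 of the 24 lists, 12 upward and 1 downward, and 5 of these held with an estimated correlation: cytokines, chemokines, interferon-stimulated genes, antigen presentation, and nitric oxide, prostaglandin and itaconate enzymes. Fry, which does not compare a list with other genes, called 18. With the preset correlation, camera also called up to 15 lists in other splits of the 6 libraries. Those splits hold libraries with and without LPS on both sides, so this number is no rate of false calls.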

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

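The tests of strand marking, of the expression trend, of scaling and of oligodendrocyte-lineage markers were chosen after the results were seen, as were the removal of the expression trend and the length and GC correction; the tests of induced neighbours, of the ribosomal protein genes on length, GC content and matched lists, and of other splits were chosen before their results. Only 10 splits of the 6 libraries into 3 and 3 exist, so no share under 0.05 is possible. The real split called 4659 genes, 1831 of them at least 2-fold, and in 1 of the 10 splits, the real one, were there as many; the highest other split called 0 in each case. For camera lists the real split gave 13 and the highest other 15, with 2 of the 10 splits as high. With an estimated correlation the real split gave 5 and the highest other 0. Every other split holds libraries with and without LPS on both sides, so the LPS difference enters its spread and partly remains between its sides. Few calls there were therefore likely in advance for genes on either strand, and these splits give no rate of false calls.

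A signal outside the main measurement appeared on the strand opposite to the annotated gene. Of 614 genes with enough opposite-strand reads, 212 were higher with LPS (edgeR, adjusted p under 0.05) and 35 lower; 1 of the 10 splits, the real one, gave as many, and the highest other gave 0. Among called genes with more opposite-strand than sense reads in each library with LPS, the 5 with the smallest p were Gm14023 (log2 fold change 6.08 ± 0.26, SE; 60 reads with FTY720 and 2801 with LPS), Mir1198 (4.20 ± 0.21), Mki67 (fitted value 7.85 ± 0.45; 1 read against 227, ratio 330, 95% counting interval 58.6 to 13090), Mid1 (3.43 ± 0.20) and Psd (3.17 ± 0.20). Near these lie the induced sense genes Il1a for Gm14023, Ptpre for Mki67, G530011O06Rik for Mid1 and Nfkb2 for Psd, and none for Mir1198.

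Incomplete strand marking during library construction was weighed first for these 212 genes. At the 163 genes whose own sense reads were not called at least 2-fold higher, the median ratio of opposite-strand to sense reads was 238.5%, above that of every one of the 100 most abundant genes (median 0.547%), which argues against mis-marked sense reads there. At the other 49 the median was 1.05%, within the range of those abundant genes, so mis-marked sense reads may account for many of them. Transcripts of a neighbouring gene are a candidate source for part of the calls: 62 of 210 called genes (29.5%) against 5 of 394 genes not called higher (1.27%) had a gene called at least 2-fold higher on the other strand, overlapping or ending within 10 kb upstream (odds ratio 32.4, 95% interval 12.8 to 105.3, Fisher's exact two-sided p = 8.01e-26), and without the 49 it was 54 of 161 (odds ratio 39.0). Where the genes overlap, sense reads of the neighbour can be counted as opposite-strand reads of the gene. Both calls also come from the same libraries, so this link is partly built in. Overlapping neighbours and those within 10 kb were not counted apart. The other called genes have no such neighbour, and an LPS response of antisense transcripts stays open and untested.

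Abundant genes were higher and scarce genes lower with LPS: the median log2 fold change was 0.60 in 714 genes above 7 log2 CPM and -0.28 in 4132 genes at or under 4, a gap of 0.89, and with genes ranked by the FTY720 libraries alone 0.60. Removing trends on length and GC content left a gap of 0.79 (95% bootstrap interval 0.75 to 0.84), which argues against these trends as the whole cause, while a background of genomic DNA in the FTY720 libraries stays open, because opposite-strand reads at genes not called there were 1.27 times as frequent with LPS under TMM scaling but 1.02 times with total library size alone, where FTY720 replicate 3 had the highest share (1.28%). Ribosomal protein genes, a group chosen after their values were seen, follow the trend: 71 of 73 were higher (median 0.67), at percentile 74.0 of lists matched on length and mean expression (median 0.62), so short, abundant transcripts moving as a class may account for them. After length and GC correction 51 were called higher and 1 lower (median 0.34), which leaves that explanation open. With total library size alone 1 was called higher (median 0.33), so the number of calls depended on scaling. Their median lay 0.69 above that of all genes there (95% bootstrap interval 0.66 to 0.71), and 0.71 above it with TMM factors. A scaling factor moves every gene alike, so this distance could hardly change and does not test scaling as a cause. A change in total RNA per cell with LPS, which these libraries cannot measure, and a difference in library quality (unmapped reads 26.8% with LPS and 24.8% without) were not tested.

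Oligodendrocyte-lineage markers were lower with LPS in 6 of 7 genes (camera adjusted p = 0.125 with an estimated correlation), in cultures of which more than 92% of cells were CD11b-positive. The most abundant one, Mbp (1359 reads against 534), stood at -0.80 on the log2 scale. Mbp and Cspg4 were named outside the naming rule, after their values were seen. A lower share of all other cell types would lower their markers alike, but 21 astrocyte, fibroblast, mural, endothelial and neuron markers averaged -0.04 against -1.25 for 7 oligodendrocyte-lineage markers (difference -1.20, exact two-sided permutation p = 0.00174). This test treats marker genes as independent units, although markers of 1 cell type can move together. The 21 markers moved in both directions, from Slc1a2 at -1.30 to Cdh5 at 1.62. Their mean therefore does not show that the share of each of these cell types was unchanged. Of the 21, the 6 neuron markers averaged -0.71, with 4 lower. They could not be told apart from the oligodendrocyte-lineage markers (exact two-sided permutation p = 0.185), so a lower share of both kinds of cell stays open as a partial cause. Fewer oligodendrocyte-lineage cells would lower their markers by 1 common factor, but the edgeR estimates ranged from Cspg4 at -0.13 to Olig2 at -2.47, beyond their standard errors (Cochran's Q 40.2, chi-square p = 4.19e-07), which argues against a loss of these cells as the whole cause. A change of transcript levels within such cells, alone or with some loss of cells, may remain, and a direct effect of LPS on such cells was not tested.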

How the results depend on the processing

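Among the alternatives, removing the expression trend, the length and GC correction, leaving out rRNA-like genes and summing replicates 1 and 2 were chosen after the data were seen. Counts of called genes and of called lists stayed within 1.5 times the main ones except as follows. With total library size alone, 761 genes were higher, 556 at least 2-fold higher and 1826 at least 2-fold lower, where the median of all genes shifted to -0.36. The median lay at -0.17 with upper-quartile factors and -0.11 after length and GC correction. DESeq2 called 1274 genes lower, and the cause was not tested. With the expression trend removed, 630 genes were at least 2-fold lower, Actb turned to -0.47 and the lysosome list turned downward (adjusted p = 0.386); that setting removes such shifts by construction, and 45 genes were called with the opposite sign. With an estimated correlation 5 lists were called in place of 13, and the cause was not tested.

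Without each library in turn, 2043 to 2722 genes were higher, 1702 to 2495 lower, 890 to 970 at least 2-fold higher and 931 to 1092 at least 2-fold lower, and camera called 13 to 14 lists. Without FTY720 replicate 3, 2722 were higher and 2495 lower. The replicate numbers gave no pairs: deviations of same-numbered libraries correlated at -0.05, -0.02 and -0.11, and with a replicate block 2292 genes were higher and 2174 lower. With unstranded counts 4 called genes changed sign; no other alternative but the removal of the expression trend gave an opposite call. Of the named genes, P2ry12, Aif1, Pf4, Actb, Cd36, Itgam and Ms4a7 lost their call in at least 1 alternative, and Fn1 and Acta2 gained one. In simulated libraries of this size and number, with far fewer changed genes than were called here, 34.4% of 1.5-fold changes were called.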

Other observations

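Further groups were defined by gene symbol after the data were seen, and camera called none of them with an estimated correlation. Regulators of G protein signalling (Rgs) were lower in 8 of 10 tested genes and higher in 1, with a median log2 fold change of -1.04 (camera adjusted p = 0.0181; adjusted p = 0.388 with an estimated correlation). Zinc finger genes named Zfp were lower in 81 of 262 and higher in 28 (median -0.29, camera adjusted p = 0.0181, and 0.445 with an estimated correlation). With total library size alone 101 of them were lower and 3 higher (median -0.61). Translation initiation factors (Eif) were higher in 21 of 52 and lower in 2 (0.29; adjusted p = 0.026; adjusted p = 0.479 with an estimated correlation), although with total library size alone 4 were higher and 3 lower. Proteasome subunits were higher in 17 of 46 and lower in 0 (0.28, camera adjusted p = 0.227), and with total library size alone 0 were called. After length and GC correction 8 of them were higher and 6 lower (median -0.01).

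Ribosomal protein genes took 1.46% to 1.71% of scaled reads in the FTY720 libraries and 2.44% to 2.62% in those with LPS. Transcript length and GC content accounted for 42.3% of the variance of the deviations of FTY720 replicate 3 from the other 2 FTY720 libraries, for 15.5% and 27.5% in replicates 1 and 2, and for 0.572% to 2.87% in the libraries with LPS.

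Heatr9 had reads only in the libraries with LPS and lies downstream of Ccl5 on the same strand, so read-through beyond strongly induced genes was tested as a hypothesis, with the prediction set before the result. Over 25 genes within 10 kb downstream of genes at least 8-fold higher the mean log2 fold change was 2.16 (SD 2.76), and over 25 genes upstream 2.34 (SD 2.38), a difference of -0.18 (one-sided permutation p = 0.596); 14 downstream and 20 upstream genes were called higher. Without Heatr9, which prompted the test, in a comparison made after that result, the downstream mean was 1.79 and the difference -0.55 (one-sided permutation p = 0.806). The downstream genes were not higher than the upstream ones, but the difference lies within its spread, so read-through at Heatr9, whose reads came to 11.8% of those of Ccl5, may still occur.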
